A study of Homo sapiens with 12 samples.

How the data were processed

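The series holds 12 libraries of polyadenylated RNA from the human glioma cell lines U251 and U87, sequenced on an Illumina instrument, with 3 libraries for each line with artesunate (180 µM in U251, 24.08 µM in U87) and 3 without. The labels give day 9 for all samples and 24 h of treatment for the artesunate samples, and name artesunate as the treatment, while the extraction text names artemisinin. The control label names culture medium only, and a solvent control is not stated. Replicate numbers come from the sample titles. The labels do not say whether the replicates are separate cultures or whether a number links a treated to a control sample, so p values measure the spread between samples, which may be technical. No sequencing batch is given. According to the series text the authors cleaned reads with fastp, aligned them with HISAT2 2.1.0 to GRCh38 with Ensembl release 91 gene models, quantified them with StringTie 1.3.3b, and compared groups with TMM factors and edgeR 3.30.3. The step that made whole-number counts and the strandedness of the counting are not stated.

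The deposited table holds 58302 genes with whole-number counts per library, which the authors did not normalize per the file headers. It also holds FPKM values that the authors computed after TMM normalization, the authors' log2 fold changes of 3 comparisons, their p values and adjusted p values, and other columns with the authors' call of up, down or neither. The authors' calls were checked: each called gene, and only these, had an absolute log2 fold change of at least 1, p under 0.05 and a group mean of at least 1 FPKM in the higher group. They made 269 calls in U251, of which 147 were also called here, 3971 in U87 (3751) and 4502 between the controls (4296). Symbols, biotypes and coordinates came from the deposited table. Gene identifiers were matched to GENCODE release 29 for the GC content and length of the longest transcript and to check the positions. Of the 58302 identifiers 58039 were found, 97.60% of them with the same position, and 99.6% of the tested genes had a GC value.

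Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17150 of the 35237 genes with a count. TMM factors were computed, and a quasi-likelihood model with 1 mean for each of the 4 groups was fitted to all 12 libraries (common biological coefficient of variation 0.183). Artesunate against control was tested in each line, the difference of these effects between the lines was tested as an interaction (U251 minus U87), and U251 controls were compared with U87 controls. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over the genes of each comparison, and numbers of genes of a list that rose, fell or lay higher or lower are numbers of called genes. Standard errors are the absolute log2 fold change over the square root of the quasi-likelihood F. CPM are given as mean and SD of 3 libraries. Library totals of 13631985 to 17314284 put 3 counts at about 0.179 CPM in U87 controls and 0.190 CPM in U251 controls, the floor. Against a group with 0 counts the fold is given as a lower bound computed at the floor, against a group with few counts the ratio is given with its 95% exact binomial interval from the summed counts, and where both groups were at or under the floor no fold is given. Intervals and floors cover counting error only.

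Before the data were examined, 34 gene lists were fixed, and 32 with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) with its preset correlation of 0.01, adjusted over the lists in each comparison. The lists cover the integrated stress response, endoplasmic reticulum chaperones, NRF2 targets, ferroptosis, iron, heme, metallothioneins, heat shock, p53 targets, apoptosis, DNA replication, mitosis, histones, cholesterol, fatty acids, glycolysis, hypoxia, nuclear and mitochondrial respiratory chain genes, ribosomal proteins, ribosome biogenesis, proteasome, autophagy, inflammation, interferon, immediate early genes, extracellular matrix, YAP and TGF-beta targets, and markers of astrocytes, neurons, oligodendrocytes, microglia and leukocytes, endothelium and epithelium. Some genes stand in more than 1 list. Camera with an estimated correlation and fry, which asks only whether a list moves on balance one way, were alternatives.

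Named genes followed a rule fixed at the same time, and the rule's names that belong to lists not described are not printed. In each line these were the 6 raised and 6 lowered protein-coding genes with the largest fold change among called genes with a mean log2 CPM of at least 3 and every artesunate library beyond every control, the member with the smallest p in each direction from each described list, and 11 genes reported in both lines whatever their result. For the difference the rule took 5 genes per direction and for the controls 6. The mean log2 CPM was read as the mean over the 12 libraries with a prior count of 2, a reading settled after edgeR's own average had been seen. The rule also picked genes that are not reported here. Of the 75 named genes 29 overlap another tested gene, and whether counts of shared positions went to one or both is not stated. Genes with both groups of a line at or under the floor were left out of the comparison of effects between lines, a choice made after their values were seen.

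Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2's size factors, total counts without TMM factors, no filter and a stricter filter (50 counts in 3 libraries), an absolute log2 fold change of at least 1, an adjusted p under 0.01, a replicate block, only the 6 libraries compared, limma-trend on FPKM with pseudocounts of 1 and 0.1 and without a filter, and leaving out each library in turn. Fits without a library of a group that a comparison does not use, which enters it only through the filter, the factors and the shared spread, were added to the tables after the others had been seen. A correction for GC content and transcript length was added after seeing the data. It fits a spline of each library's log2 deviation on GC content (5 degrees of freedom) and log2 length (3 degrees of freedom) and enters the model as an offset, so it also removes any biological change that follows GC content.

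The procedure was tested on simulated data with 200 changed genes and 3 libraries per group, and each gene was drawn independently of the others. In the data 10005 of 17150 genes were called in U87. The simulated U87 rates without a GC trend do not cover a response that wide. The simulated list tests do not cover correlation between genes. For artesunate against control, edgeR recovered 16.4, 59.7 and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold in U251, with 4.17% false calls, and 13.4, 58.2 and 90.9% in U87, with 4.42% false calls. For the difference between lines it recovered 5.97, 31.3 and 81.8%. In U251, DESeq2 gave 16.2% and limma-trend 9.23% false calls. With 1 of 32 lists raised 1.5-fold in U251, camera with its preset correlation called 2 lists, the raised one among them, and with an estimated correlation only the raised one. With a GC trend added to simulated U87 libraries, 98.5% of the calls were false before the correction and 22.4% after it, and camera called 2 of 31 lists before it and 0 after it, with none raised. Pearson's r between libraries with the same replicate number, after removing group means, was -0.009 to 0.053. The highest r with another number was -0.023 to 0.044. The same-number r was below it in U251 replicate 2 and U87 replicate 3 and above it in the other replicates. Such small values do not decide whether numbers mark pairs. Because the labels do not say so, numbers were not taken as pairs. No sample was left out.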

Results

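Libraries of polyadenylated RNA from the human glioma cell lines U251 and U87 were compared after 24 h of artesunate and in control medium, with 3 libraries in each of 4 groups. The labelled dose was 180 µM in U251 and 24.08 µM in U87, so line and dose cannot be told apart. Library totals ran from 13631985 to 17314284 counts, and 17150 of the 58302 listed genes were tested. The first principal component of log2 CPM (counts scaled to the library total) held 79.6% of the variance and parted the lines, and the next held 10.8% and parted the U87 artesunate libraries from the U87 controls. Pearson's r across genes between libraries of a group was 0.985 to 0.987, except in U87 artesunate (0.972 to 0.981).

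The first question was which transcripts artesunate changed in U251. Stress-response and hypoxia transcripts rose and cell-cycle transcripts fell: of 17150 genes, 701 rose and 730 fell, and 162 and 70 of these changed at least 2-fold. Of the 41 genes of the integrated stress response, which are targets of the transcription factor ATF4, 34 rose and 7 were not called (36 adjusted over the list alone; median log2 fold change 0.92). Among them STC2, a secreted glycoprotein, rose by 2.44 ± 0.09 (log2 fold change ± standard error; adjusted p = 8.6e-08). CHAC1, which degrades glutathione, rose by 2.35 ± 0.38, and the stress transcription factors ATF3 and DDIT3 rose by 1.13 ± 0.22 and 1.08 ± 0.13. Of 25 targets of NRF2, the regulator of the antioxidant response, 18 rose (21 adjusted over the list alone; median 0.52). HMOX1, the heme-degrading oxygenase (ENSG00000100292, chromosome 22, 35380361 to 35394214), rose from 32.8 ± 4.09 to 211 ± 10.2 CPM (mean ± SD of 3 libraries; log2 fold change 2.69 ± 0.15, adjusted p = 3.1e-06). SLC7A11, the cystine transporter, rose by 0.86 ± 0.14.

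In U251 the hypoxia targets outside glycolysis rose in 15 of 20 genes (18 adjusted over the list alone; median 1.07), with NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022) going from 36.9 ± 2.25 to 432 ± 12.5 CPM, a log2 fold change of 3.55 ± 0.14 (adjusted p = 1.6e-07). VEGFA, the angiogenic growth factor, rose by 2.79 ± 0.21, and CA9, a membrane carbonic anhydrase, by 2.68 ± 0.36. Of 21 glycolysis genes 13 rose (18 adjusted over the list alone; median 0.69), among them HK2, which phosphorylates glucose, by 1.89 ± 0.09. Of 35 mitosis and G2/M genes 30 fell (33 adjusted over the list alone; median -0.71), and CCNB1, the mitotic cyclin B1, fell by 1.04 ± 0.08. MKI67, the gene of the Ki-67 antigen, had a log2 fold change of -0.59 ± 0.23 and was not called (adjusted p = 0.14), but was called when only the 6 U251 libraries were fitted (adjusted p = 0.0017; 0.0017 to 0.27 over all alternatives) and without U87 control 2 (adjusted p = 0.0035). Of 37 DNA replication and G1/S genes 24 fell (30 adjusted over the list alone; median -0.46), and PCNA, the replication clamp, fell by 0.66 ± 0.08.

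The 6 lists above were called by camera in U251 with adjusted p = 4.8e-36 for the integrated stress response, 3.3e-19 for NRF2, 6.8e-20 for hypoxia, 9.9e-13 for glycolysis, 8.8e-31 for mitosis and 3.4e-16 for DNA replication. With an estimated correlation the adjusted p values were 1.1e-05, 0.00012, 0.0048, 0.024, 0.0048 and 0.0093 in that order, so these calls held. The number of called genes in U251 moved from 1431 to 774, 671 and 693 without control 1, 2 and 3, to 652 and 680 without artesunate 1 and 2, and to 1047 without artesunate 3. The U87 libraries share in the estimate of spread, and the number was 1375, 1174 and 1091 without U87 control 1, 2 and 3, and 1643, 2582 and 1369 without U87 artesunate 1, 2 and 3. It was 2310 with DESeq2, 2892 when only the 6 U251 libraries were fitted, and 864 with no filter on low counts.

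**Figure D1:**
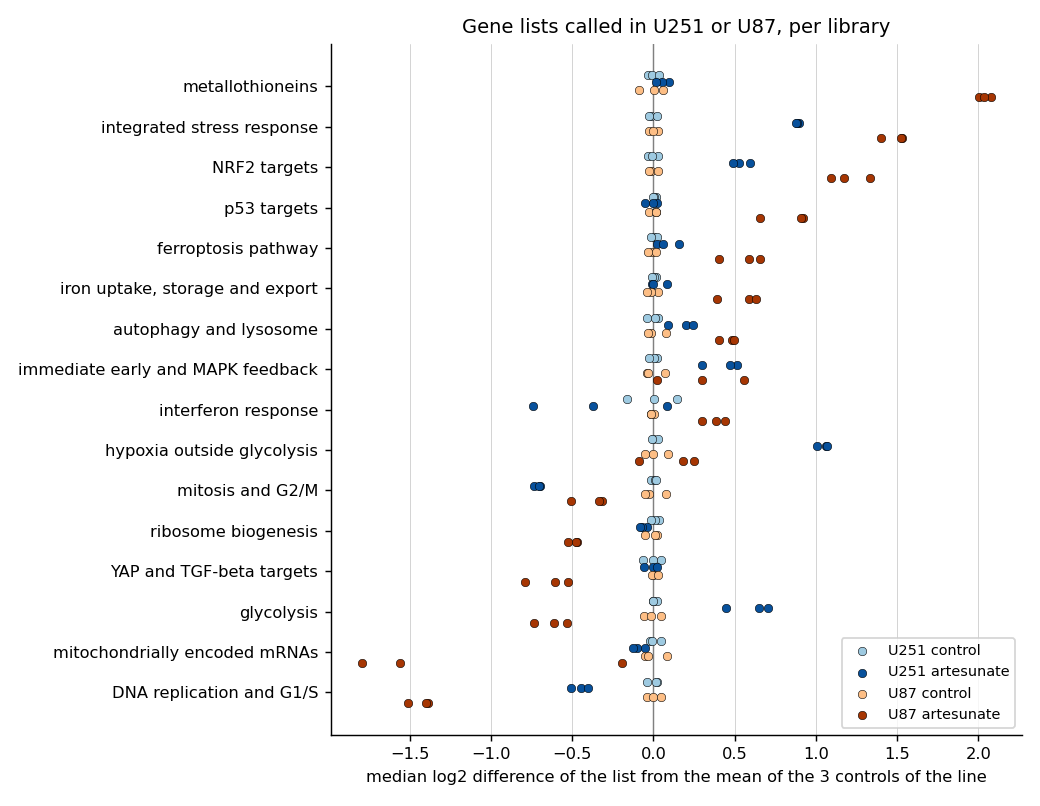
Median log2 difference of each gene list from the mean of the 3 controls of its line (horizontal axis) for every library (1 point per library, 3 per group), for the lists that camera called in U251 or U87. The integrated stress response lay at 0.87 to 0.89 in the U251 artesunate libraries and at 1.40 to 1.53 in the U87 artesunate libraries, and mitochondrially encoded mRNAs were spread from -1.79 to -0.19 in U87 artesunate.

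Smaller shifts were called for 4 more lists in U251. Of 23 immediate early and MAPK feedback genes 7 rose (9 adjusted over the list alone; median 0.38, adjusted p = 0.00026, and adjusted p = 0.19 with an estimated correlation), including DUSP1, a MAP kinase phosphatase, by 0.69 ± 0.10. Of 31 autophagy and lysosome genes 5 rose (6 adjusted over the list alone; median 0.17, adjusted p = 0.0057, and adjusted p = 0.19 with an estimated correlation), including the autophagy receptor SQSTM1 by 0.90 ± 0.18. Of 34 ferroptosis pathway genes 9 rose (9 adjusted over the list alone; median 0.09, mean 0.21, adjusted p = 0.033, and adjusted p = 0.083 with an estimated correlation). HMOX1 and SLC7A11 are among them and also stand in the NRF2 list. GPX4, the peroxidase that reduces lipid hydroperoxides, had a log2 fold change of 0.24 ± 0.15 (adjusted p = 0.38). This log2 fold change was 0.12 without control 1 and 0.36 without control 3. TFRC, the transferrin receptor, rose by 0.34 ± 0.08 and FTH1, the ferritin heavy chain, by 0.44 ± 0.10 (both adjusted p = 0.018). The ferroptosis call was lost without control 1, control 3 or artesunate 1 (adjusted p = 0.10, 0.062 and 0.093), and without U87 control 1, U87 control 2, U87 artesunate 2 or U87 artesunate 3 (adjusted p = 0.054, 0.0504, 0.089 and 0.064), and its median was 0.02 without artesunate 2. It was also lost with total counts in place of TMM (adjusted p = 0.053) and with a replicate block (adjusted p = 0.097; 2.5e-05 to 0.10 over all alternatives). The TFRC call was lost without control 2, control 3, artesunate 1 or artesunate 2 (adjusted p = 0.056, 0.078, 0.055 and 0.063), and the FTH1 call without control 2, control 3, artesunate 2 or artesunate 3 (adjusted p = 0.090, 0.092, 0.058 and 0.057), with a replicate block (adjusted p = 0.058) and on FPKM with no filter (adjusted p = 0.083; 0.0013 to 0.092 over all alternatives).

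Of 24 interferon response genes 4 fell in U251 (9 adjusted over the list alone; median -0.30, adjusted p = 0.025, and adjusted p = 0.69 with an estimated correlation). The list median was -0.38, -0.74 and 0.08 in artesunate libraries 1, 2 and 3. The list call was lost without control 1, control 3, artesunate 1 or artesunate 2 (adjusted p = 0.13, 0.079, 0.069 and 0.41), where the median was -0.16, -0.35, -0.27 and -0.04, and without U87 control 1, U87 control 2 or U87 artesunate 2 (adjusted p = 0.054, 0.0504 and 0.11). Without artesunate 3 its median was -0.53. With fry the call was lost too (adjusted p = 0.19; 1.4e-05 to 0.69 over all alternatives).

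Outside these lists, among called protein-coding genes with a mean log2 CPM of at least 3 and every artesunate library beyond every control, the largest rises in U251 included UNC5B, a netrin receptor, from 12 to 109 counts over 3 libraries (log2 fold change 3.19 ± 0.40; ratio 9.39, 95% interval 5.16 to 18.7), and DEPP1 by 3.02 ± 0.18. AC023055.1, whose span overlaps SARNP, GDF11, ORMDL2 and DNAJC14, went from 6 to 1418 counts, a ratio of 244 (95% interval 112 to 667). RHOQ, a small GTPase, fell by 1.85 ± 0.35, DNAJC15, a mitochondrial cochaperone, fell by 1.34 ± 0.14, and SPDL1, a spindle protein, fell by 1.18 ± 0.09. CYP1B1, a cytochrome P450, fell by 1.43 ± 0.36, PSME3, a proteasome activator, fell by 1.27 ± 0.33, and OLFML2B fell by 1.19 ± 0.24. The mean log2 CPM runs over both lines, so genes low in U251 could meet it by their U87 level. In the U251 libraries CYP1B1 lay at 0.556 to 4.199 CPM, OLFML2B at 0.695 to 2.43 and UNC5B at 0.122 to 2.58. In the U87 libraries they lay at 220 to 861, 32.2 to 89.3 and 27.8 to 260 CPM. The CYP1B1 call was lost without control 1, control 2, artesunate 1 or artesunate 3 (adjusted p = 0.10, 0.12, 0.077 and 0.087). The PSME3 call was lost without control 1 or 3 or artesunate 1, 2 or 3 (adjusted p = 0.11, 0.13, 0.11, 0.11 and 0.089), and the OLFML2B call without artesunate 2 (adjusted p = 0.056). The CYP1B1 call was also lost when only the 6 U251 libraries were fitted (adjusted p = 0.075) and without U87 control 3 (adjusted p = 0.052), and the PSME3 call with a replicate block (adjusted p = 0.084) and without U87 control 2 or 3 (adjusted p = 0.05005 and 0.053). With limma-trend on log2(FPKM + 1), the calls of UNC5B (0.37), CYP1B1 (-0.24), PSME3 (-1.04) and OLFML2B (-0.20) were lost (adjusted p = 0.16, 0.090, 0.052 and 0.18). That setting pulls low values toward 0, but PSME3 was not low (73.9 to 237 CPM in U251). PSME3 stood at 230, 84.3 and 237 CPM in U251 controls 1, 2 and 3 and at 73.9 to 77.8 CPM after artesunate. Its fall thus rests mostly on controls 1 and 3. Why these calls were lost was not tested. The PSME3 call was lost with FPKM + 0.1 as well (adjusted p = 0.057). Over all alternatives the adjusted p ran from 2.5e-09 to 0.32 for UNC5B, 0.00022 to 0.17 for CYP1B1, 0.0015 to 0.13 for PSME3 and 0.0014 to 0.33 for OLFML2B.

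The other lists were not called in U251, with camera adjusted p from 0.30 to 0.96. Of the iron genes 3 of 16 rose, of heme metabolism 2 of 18, of p53 targets 2 of 25 and of apoptosis regulators 2 of 26. CDKN1A, the cyclin-dependent kinase inhibitor p21, had a log2 fold change of 0.33 ± 0.20 (adjusted p = 0.35; adjusted p = 0.041 when only the 6 U251 libraries were fitted, 0.038 without U87 artesunate 2, and 0.038 to 0.64 over all alternatives). Of the metallothionein list 1 of 6 rose, the zinc exporter SLC30A1, by 0.55 ± 0.10. Of endoplasmic reticulum chaperones 1 rose and 1 fell of 24, of cytosolic heat shock genes 1 and 2 of 17, of fatty acid synthesis 1 and 1 of 11, of cytosolic ribosomal proteins 1 and 1 of 39, and of inflammatory genes 2 and 1 of 21. Of extracellular matrix genes 4 rose and 1 fell of 29, and of YAP and TGF-beta targets 4 and 1 of 16, where F3, the tissue factor, rose by 1.18 ± 0.09 and TGFB2 fell by 0.87 ± 0.12. In ribosome biogenesis 1 of 26 fell. Of marker lists, 1 rose and 2 fell of 14 astrocyte and glioma markers, 1 of 7 neuron markers and 1 of 7 endothelial markers fell, and 1 of 5 epithelial markers rose. The list medians were -0.17 for 11 histones, 0.02 for 25 cholesterol genes, -0.07 for 34 nuclear-encoded respiratory chain genes, -0.08 for 13 mitochondrially encoded mRNAs and -0.08 for 27 proteasome subunits. HMGCS1, an enzyme of cholesterol synthesis, had a log2 fold change of -0.01 ± 0.23 (adjusted p = 1), and its sign turned without control 2 (0.01) and without artesunate 1 (0.06). Oligodendrocyte and microglia or leukocyte markers had 2 and 3 tested members and were not tested as lists.

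The next question was which transcripts artesunate changed in U87. Of 17150 genes, 5000 rose and 5005 fell, and 1969 and 2907 of these changed at least 2-fold. In the integrated stress response 36 of 41 genes rose and 2 fell (38 adjusted over the list alone; median 1.47, adjusted p = 6.3e-13). SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349) rose from 28.9 ± 5.13 to 1327 ± 52.03 CPM, a log2 fold change of 5.52 ± 0.17 (adjusted p = 6.4e-09). TRIB3, a pseudokinase, rose by 3.48 ± 0.14, CTH, which makes cysteine, by 3.69 ± 0.14, PSAT1 of serine synthesis by 2.84 ± 0.08, DDIT3 by 2.02 ± 0.13 and CHAC1 by 2.34 ± 0.39. ATF3 rose by 0.81 ± 0.21, with adjusted p = 0.0063, and adjusted p = 0.059 after a correction for GC content and transcript length (0.0018 to 0.059 over all alternatives). CEBPB, a transcription factor, fell by 0.86 ± 0.13 and was at 0.60 after that correction. Of 25 NRF2 targets 20 rose and 1 fell (21 adjusted over the list alone; median 1.25, adjusted p = 1.1e-07), with HMOX1 rising by 1.62 ± 0.15.

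All 6 tested genes of the metallothionein list, which bind or export metals, rose in U87 (6 adjusted over the list alone; median 2.04, adjusted p = 9.3e-05), with MT1F rising by 2.32 ± 0.08. MT1 genes are close paralogs, so single members are less certain than the group. Of 34 ferroptosis pathway genes 20 rose and 6 fell (27 adjusted over the list alone; median 0.67, adjusted p = 0.0067), and PCBP1, an iron chaperone, fell by 1.13 ± 0.08. GPX4 had a log2 fold change of -0.26 ± 0.15 (adjusted p = 0.15), and 0.88 after the GC and length correction (adjusted p = 0.00016; 0.00016 to 0.44 over all alternatives). Of 16 iron genes 11 rose and 1 fell (12 adjusted over the list alone; median 0.58, adjusted p = 0.0097, and adjusted p = 0.18 with an estimated correlation). CYBRD1, an iron reductase, rose by 1.69 ± 0.11, and STEAP3, an endosomal iron reductase, fell by 1.42 ± 0.10. FTH1 rose by 0.65 ± 0.10. TFRC rose by 0.49 ± 0.08 (adjusted p = 0.00017) and was at -0.09 after the correction (adjusted p = 0.12; 1.8e-07 to 0.12 over all alternatives).

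DNA replication and G1/S genes fell in 36 of 37 members in U87 (36 adjusted over the list alone; median -1.44, adjusted p = 1.4e-15). MCM5 of the replicative helicase (ENSG00000100297, chromosome 22, 35400063 to 35425430) went from 276 ± 22.2 to 39.7 ± 4.38 CPM and fell by 2.80 ± 0.10 (adjusted p = 1.1e-08). Of 35 mitosis and G2/M genes 21 fell (21 adjusted over the list alone; median -0.38, adjusted p = 9.3e-05, and adjusted p = 0.28 with an estimated correlation), and CDC20, an activator of the anaphase-promoting complex, fell by 2.04 ± 0.09. MKI67 fell by 1.21 ± 0.23, and by 0.79 without control 2. Of 25 p53 targets 15 rose and 8 fell (23 adjusted over the list alone; median 0.88, mean 0.42, adjusted p = 0.036, and adjusted p = 0.13 with an estimated correlation). TP53INP1 rose by 2.38 ± 0.10, while BAX, a pro-apoptotic gene, fell by 1.35 ± 0.13. CDKN1A had a log2 fold change of 0.43 ± 0.20 (adjusted p = 0.089), 0.60 without artesunate 1 (adjusted p = 0.019) and 0.065 without artesunate 2 (adjusted p = 0.62). The p53 call was lost without artesunate 2 (adjusted p = 0.070) and with a replicate block (adjusted p = 0.064; 1.5e-08 to 0.13 over all alternatives).

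In U87, 15 of 21 glycolysis genes fell and 3 rose (18 adjusted over the list alone; median -0.66, adjusted p = 0.0040, and adjusted p = 0.36 with an estimated correlation). After the GC and length correction the median was -0.33 and the list was not called by camera (adjusted p = 0.098). PFKFB4, which makes an activator of phosphofructokinase, fell by 2.28 ± 0.11, and the glucose transporter SLC2A3 rose by 2.04 ± 0.12. Of 20 hypoxia targets outside glycolysis 7 rose and 6 fell and the list was not called (median 0.23, adjusted p = 0.52). BNIP3L, a mitophagy receptor, rose by 2.03 ± 0.15 and ANGPTL4, a lipase inhibitor, fell by 2.26 ± 0.38. Of 26 ribosome biogenesis genes 5 rose and 15 fell (20 adjusted over the list alone; median -0.57, adjusted p = 0.043, and adjusted p = 0.40 with an estimated correlation), where BOP1, a processing factor of ribosomal RNA, fell by 2.63 ± 0.15 and RRN3, a factor of RNA polymerase I, rose by 0.80 ± 0.10. That call was lost without artesunate 2 (adjusted p = 0.13) and with a replicate block (adjusted p = 0.073; 4.3e-06 to 0.40 over all alternatives). Of 16 YAP and TGF-beta targets 2 rose and 9 fell (12 adjusted over the list alone; median -0.62, adjusted p = 0.030, and adjusted p = 0.18 with an estimated correlation), where AXL, a receptor kinase, fell by 1.36 ± 0.08 and LATS2, a kinase of the Hippo pathway, rose by 0.86 ± 0.08.

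Of the 13 mitochondrially encoded mRNAs 9 fell in U87 (9 adjusted over the list alone; median -0.97, adjusted p = 0.0075, and adjusted p = 0.67 with an estimated correlation). MT-CO3, a subunit of cytochrome c oxidase, fell by 1.79 ± 0.18. These mRNAs took 3.49 ± 0.189% of the counts in U87 controls and 1.33, 2.93 and 1.44% in artesunate libraries 1, 2 and 3, where the list median was -1.79, -0.19 and -1.56. Without artesunate 2 the median was -1.68. The mitochondrial ribosomal RNAs took 0.382 ± 0.0442% in U87 controls and 0.477 ± 0.0170% after artesunate.

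Among the genes that met the same conditions, the largest rises in U87 outside these lists were KLHL24 by 3.91 ± 0.30, EREG, an epidermal growth factor receptor ligand, by 3.86 ± 0.21, and GPR1 by 3.72 ± 0.66. The lowest log2 fold changes among them were those of CAMK2N2 (-3.76 ± 0.28), RTEL1-TNFRSF6B (-3.69 ± 0.48), FKBP2 (-3.65 ± 0.21), the histone gene H2AFX (-3.46 ± 0.29), ELFN2 (-3.43 ± 0.24) and PKMYT1, an inhibitory kinase of CDK1 (-3.42 ± 0.33). RTEL1-TNFRSF6B is a read-through gene that overlaps its neighbours. HMGCS1 rose by 0.74 ± 0.23 (adjusted p = 0.015). That call was lost without control 2 (0.64, adjusted p = 0.064), without artesunate 1 (0.45, adjusted p = 0.076), when only the 6 U87 libraries were fitted (adjusted p = 0.066), with limma-trend on log2(FPKM + 0.1) (adjusted p = 0.052) or on log2(FPKM + 1) with no filter (adjusted p = 0.11), and after the GC and length correction (adjusted p = 0.74; 0.00019 to 0.74 over all alternatives).

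The other lists were not called in U87, with camera adjusted p from 0.073 to 0.93, and most had members that moved both ways. The genes that rose and fell were 14 and 5 of 24 endoplasmic reticulum chaperones, 5 and 7 of 18 heme genes, 5 and 5 of 17 cytosolic heat shock genes, 10 and 5 of 26 apoptosis regulators and 3 and 4 of 11 histones. They were 11 and 11 of 25 cholesterol genes, 1 and 4 of 11 fatty acid synthesis genes, 10 and 10 of 34 nuclear-encoded respiratory chain genes, 10 and 12 of 39 cytosolic ribosomal proteins and 15 and 6 of 27 proteasome subunits. In the signalling lists they were 16 and 9 of 31 autophagy and lysosome genes, 8 and 5 of 21 inflammatory genes, 7 and 4 of 24 interferon genes, 11 and 4 of 23 immediate early genes and 6 and 13 of 29 extracellular matrix genes. Of the markers they were 2 and 5 of 14 for astrocyte and glioma, 2 and 2 of 7 for neuron and 1 and 1 of 5 for epithelium, while 4 of 7 endothelial markers fell.

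Fold changes followed the GC content of the transcript in both lines, with opposite signs. Across the tested genes Spearman's rho of log2 fold change and GC content was -0.628 in U87 and 0.412 in U251 (genes are not independent replicates). From the lowest to the highest of 5 GC bins the median log2 fold change was 0.70, 0.42, 0.11, -0.40 and -1.16 in U87 and -0.19, -0.10, -0.01, 0.08 and 0.25 in U251. In the highest bin the U87 artesunate libraries lay at -1.35, -0.74 and -1.22 and the U87 controls at -0.12, 0.11 and 0.02. After the correction of each library for GC content and length, 7809 genes were called in U87 (3364 higher and 4445 lower), of which 5686 had been called in the same direction before and 434 in the other. Of the higher genes 979, and of the lower 1611, then changed at least 2-fold. In U251, 1576 genes were called after it against 1431 before, with 1039 called in the same direction both times. The corrected U87 medians were 1.46 for the integrated stress response, 1.25 for NRF2, 2.08 for metallothioneins, -1.41 for DNA replication, -0.88 for mitosis, 0.51 for ferroptosis, 0.30 for iron, 0.45 for p53, -1.25 for mitochondrially encoded mRNAs, -0.45 for ribosome biogenesis and -0.77 for YAP and TGF-beta targets, all called. Glycolysis in U87 was then at -0.33 and not called (adjusted p = 0.098), with quartiles of -0.59 and 0.08 after and -1.15 and -0.27 before. The autophagy and immediate early lists, not called by camera before the correction, were called after it at 0.40 and 0.44 (adjusted p = 1.1e-05 and 0.0035), and by fry before it (adjusted p = 2.6e-05 and 0.0034). Single genes moved as well, among them CAMK2N2 to -2.07, RTEL1-TNFRSF6B to -2.44, FKBP2 to -2.36, H2AFX to -2.06, PKMYT1 to -2.04, BOP1 to -1.27, ANGPTL4 to -1.16, STEAP3 to -0.85, PCBP1 to -0.72, BAX to -0.57, RRN3 to 0.22, CYBRD1 to 1.11 and BNIP3L to 1.34, all called. CDKN1A was called at 1.08 (adjusted p = 7.3e-05; 7.3e-05 to 0.62 over all alternatives).

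**Figure D2:**
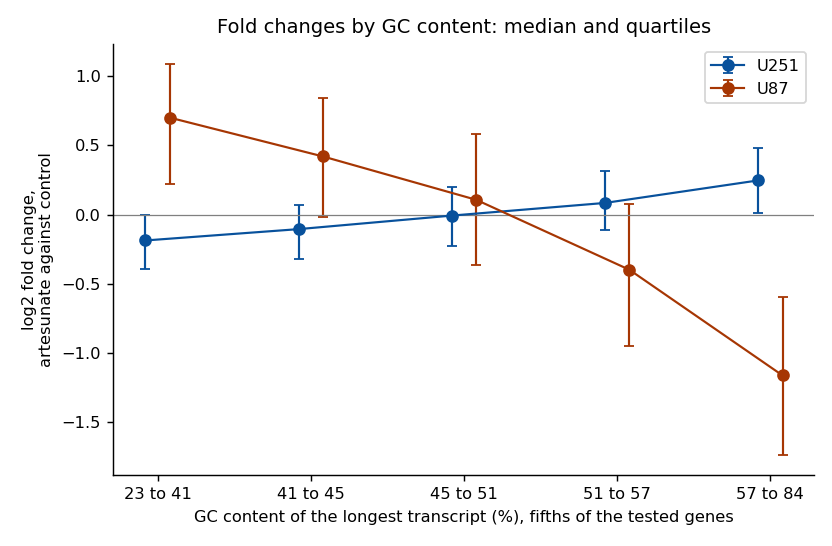
Log2 fold change of artesunate against control (vertical axis) for 5 equal bins of genes by GC content of the longest transcript (horizontal axis, %), with the median as points and the quartiles as bars, for U251 and U87. The U87 medians go from 0.70 in the lowest bin to -1.16 in the highest, and the U251 medians from -0.19 to 0.25.

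The difference of the artesunate effect between the lines was tested as U251 minus U87. Of 17150 genes, 4132 had a higher and 4346 a lower effect in U251. In the DNA replication list 28 of 37 genes were called above 0 (median 0.97, adjusted p = 2.9e-09; 28 adjusted over the list alone), in glycolysis 17 of 21 (1.17, adjusted p = 1.3e-06; 17). In metallothioneins 5 of 6 were called below 0 (-2.02, adjusted p = 0.00026; 5). Of hypoxia targets 13 were called above and 3 below 0 of 20 (0.99, adjusted p = 0.0091; 16), of the integrated stress response 6 and 19 of 41 (-0.44, adjusted p = 0.017; 25) and of NRF2 targets 5 and 14 of 25 (-0.52, adjusted p = 0.022; 21). With an estimated correlation these 6 calls were lost, with adjusted p = 0.080, 0.14, 0.080, 0.30, 0.080 and 0.10 in that order. Among single genes, PFKFB4 rose by 1.43 ± 0.11 in U251 and fell by 2.28 ± 0.11 in U87, a difference of 3.71 ± 0.15 (adjusted p = 1.5e-07). CA9 differed by 4.35 ± 0.49, FKBP2, a peptidyl-prolyl isomerase, by 4.59 ± 0.28 and CCDC9B by 4.19 ± 0.47. SLC7A11 differed by -4.66 ± 0.21, EREG by -5.01 ± 0.83, RHOQ by -4.34 ± 0.49 and KLHL24 by -3.77 ± 0.38. AC023055.1 differed by 7.11 ± 0.41, a fitted value that rests on 6 counts in the U251 controls, and AC004922.1, which overlaps PDAP1, ARPC1A and ARPC1B, by 5.90 ± 1.41. EREG had 12 and 5 counts in U251, so its difference rests on the U87 change. PDE1C, also picked by the rule for named genes, had 0 and 4 counts in U87, so no fold is given for that line.

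Of 13 mitochondrially encoded mRNAs 5 were called above 0 (5 adjusted over the list alone) with a median difference of 0.93, and of 16 YAP and TGF-beta targets 8 were called above and 2 below 0 (10), with a median of 0.35 (both adjusted p = 0.040, and adjusted p = 0.67 and 0.19 with an estimated correlation). The mitochondrial call was lost without U251 control 1, U87 control 1, U87 artesunate 1 or U87 artesunate 3 (adjusted p = 0.056, 0.063, 0.074 and 0.083), with medians of 0.92, 0.84, 0.58 and 0.65, and without U87 artesunate 2 the median was 1.52. The YAP and TGF-beta call was lost without U87 control 1, U87 artesunate 1 or U87 artesunate 3 (adjusted p = 0.051, 0.059 and 0.054), with medians of 0.52, 0.37 and 0.68. Its median was 0.83 without U87 artesunate 2 and 0.57 without U251 artesunate 3. With a replicate block both calls were lost (adjusted p = 0.0501 each), and with fry the mitochondrial call (adjusted p = 0.10; 3.8e-06 to 0.67 over all alternatives). After the GC and length correction 5113 genes differed between the lines, of which 3522 had been called in the same direction before and 280 in the other. The median difference was then -0.86 for the integrated stress response and 0.72 for glycolysis, and mitosis, at -0.33 and not called before (adjusted p = 0.13), was called at 0.24 (adjusted p = 0.048). The other corrected medians of called lists were 1.08 for DNA replication, -2.36 for metallothioneins, 1.34 for hypoxia targets, -0.59 for NRF2, 1.35 for mitochondrially encoded mRNAs, 0.49 for YAP and TGF-beta targets, -0.25 for ferroptosis, -0.43 for p53, 0.43 for ribosome biogenesis, -0.38 for autophagy and -0.54 for interferon. FKBP2 differed by 3.05 after the correction.

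**Figure D3:**
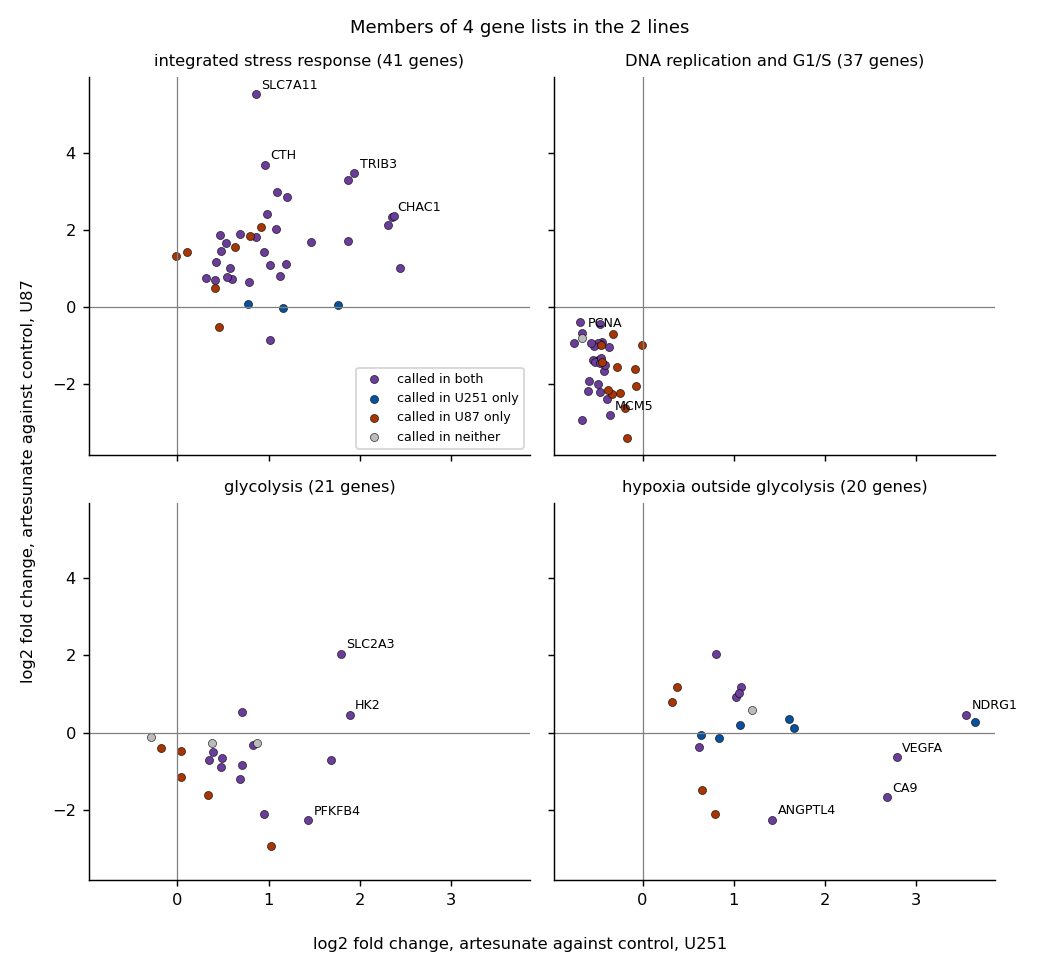
Log2 fold change of artesunate against control in U251 (horizontal axis) and in U87 (vertical axis) for the tested members of 4 gene lists, coloured by the line in which edgeR called them. PFKFB4 of the glycolysis list lies at 1.43 in U251 and -2.28 in U87, and SLC7A11 of the integrated stress response list at 0.86 and 5.52.

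Across the tested genes the fold changes of the lines, which share no libraries, had a Spearman's rho of -0.176 and a Pearson's r of -0.102, and genes are not independent replicates. After the GC and length correction rho was 0.131 and r 0.0782. There were 253 genes higher in both lines (204.4 if the calls were independent), 232 lower in both (213.0), 287 higher in U251 and lower in U87 (204.6), and 236 lower in U251 and higher in U87 (212.8). After the correction these were 437, 479, 191 and 73 (166.1, 188.9, 219.5 and 143.0 if independent). Before the correction HMOX1, DDIT3, ATF3, CHAC1, SLC7A11, TFRC and FTH1 of the genes reported in both lines whatever their result rose in both. After it, TFRC was at -0.092 in U87, and ATF3 was at 0.56 there and not called (adjusted p = 0.059). The U251 calls of TFRC and FTH1 were also lost without some single U251 libraries. The overlap counts moved with single libraries. Without U251 artesunate 1, artesunate 2, control 2 and control 3 the genes higher in both were 159, 167, 162 and 162. Without U251 artesunate 1, artesunate 2, control 1, control 2 and control 3 the genes lower in both were 139, 145, 147, 130 and 149, those higher in U251 and lower in U87 were 103, 106, 150, 114 and 104, and those of the reverse kind were 61, 67, 84, 66 and 72. Without U87 artesunate 2 the last 2 counts were 757 and 523, and the last was 155 and 128 without U87 control 2 and 3.

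**Figure D4:**
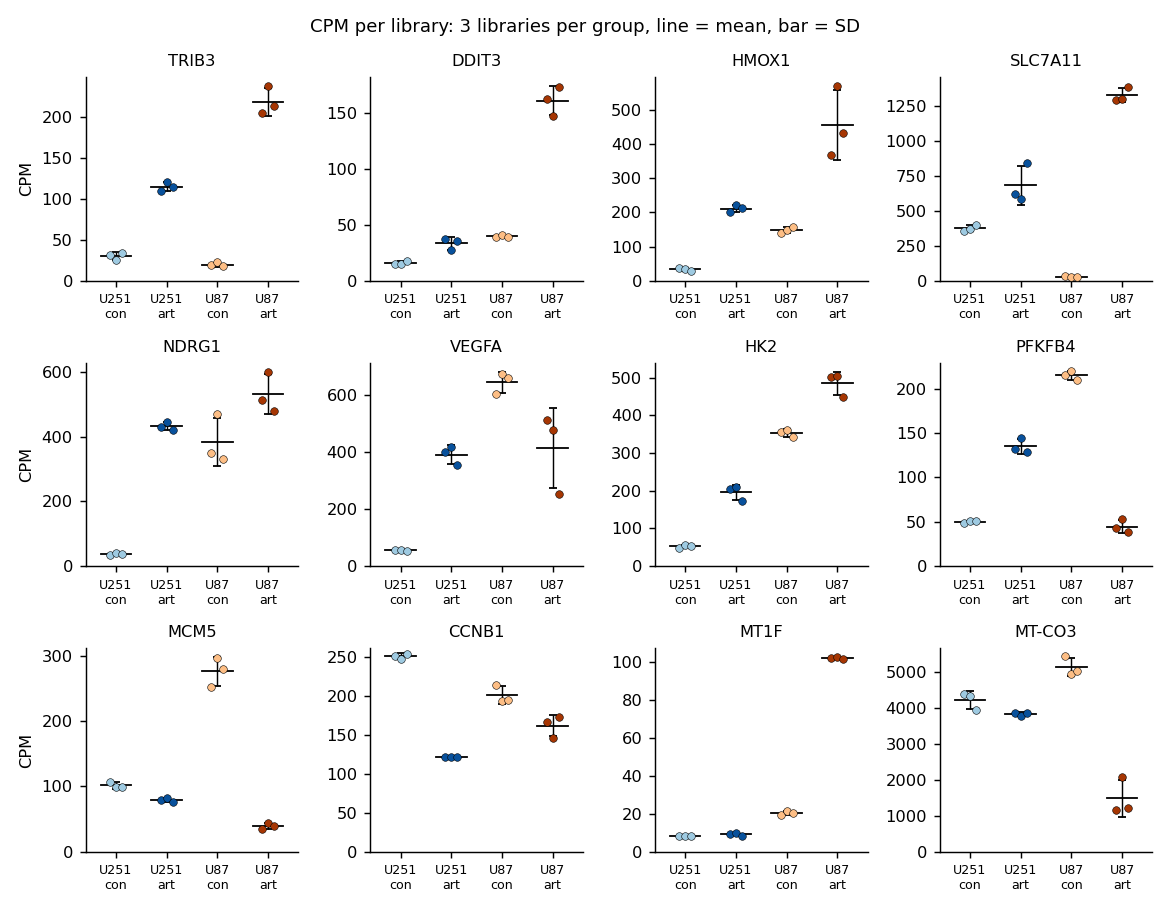
CPM of 12 genes in each library (points), with the mean (line) and SD (bar) of the 3 libraries of each group (con, control; art, artesunate). SLC7A11 went from 28.9 to 1327 CPM in U87 and from 375 to 681 CPM in U251, and HK2 from 52.8 to 196 CPM in U251.

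The last comparison asked how the lines differed without artesunate, as U251 controls minus U87 controls. Of 17150 genes, 5573 were higher and 5542 lower in U251. Inflammatory and NF-kB genes were called lower in U251 in 18 of 21 members and higher in 2 (20 adjusted over the list alone; median -2.39, adjusted p = 0.00013). CSF3, a myeloid growth factor, was 2950-fold lower in U251 (95% interval of the ratio 1842 to 5065). Glycolysis genes were called lower in 17 of 21 and higher in 2 (19 adjusted over the list alone; median -0.69, adjusted p = 0.0022), immediate early genes lower in 15 of 23 and higher in 2 (17; -1.35, adjusted p = 0.0038) and hypoxia targets lower in 14 of 20 and higher in 2 (17; -1.27, adjusted p = 0.0086). Mitosis genes were called higher in 24 of 35 and lower in 4 (28; 0.45, adjusted p = 0.0061), and DNA replication genes lower in 19 of 37 and higher in 3 (22; -0.36, adjusted p = 0.044). With an estimated correlation the calls of these 6 lists were lost, with adjusted p = 0.12, 0.33, 0.33, 0.33, 0.42 and 0.43 in that order. The DNA replication call was also lost without U251 control 3 (adjusted p = 0.059), without U87 control 2 (adjusted p = 0.052) and after the GC and length correction (adjusted p = 0.092). After the correction the mitosis median was 0.21 and the glycolysis median -0.45, both called, and NRF2 targets (0.66, adjusted p = 0.024), cholesterol genes (0.41) and extracellular matrix genes (-1.001, both adjusted p = 0.041) were called too. Without U251 control 2 the number of called lists was 10 in place of 6.

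Several genes were present in 1 line and at or near 0 counts in the other. NEFL, the neurofilament light chain (ENSG00000277586, chromosome 8, 24950955 to 24957110), stood at 2594 ± 15.4 CPM in U251 controls and 0 counts in U87 controls, at least 14515-fold higher against a floor of 3 counts per library. PDE1C, a phosphodiesterase, was at least 3802-fold higher in U251, and TFPI2, a protease inhibitor, at least 3406-fold higher in U87. In U251, CNR1, the cannabinoid receptor, was 5105-fold higher (95% interval 1994 to 18739). Its few counts in the U87 controls were all in control 1 (0.224 CPM, and 0 in controls 2 and 3), so this ratio rests on 1 library. Also higher in U251 were the integrins ITGB4 and ITGB8, 1407-fold (991 to 2071) and 501-fold (419 to 605), and THBS1, thrombospondin 1, 860-fold (681 to 1104). In U87, FLNC, a filamin, was 19944-fold higher (8546 to 61424), PLTP 1417-fold (859 to 2532), COL6A3, a collagen VI chain, 753-fold (661 to 862) and EREG 636-fold (364 to 1232).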

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

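Of the tests in this part, the correction for GC content and transcript length, the comparison of the highest GC bin between libraries and the count of splits that keep the U87 groups apart were chosen only after the result was seen. Each value in this paragraph and the next is a log2 difference of the artesunate effect, U251 minus U87, that passed a test of the difference itself, and line and dose differ together. By list medians these were DNA replication 0.97, glycolysis 1.17, metallothioneins -2.02, hypoxia targets 0.99, the integrated stress response -0.44, NRF2 targets -0.52, mitochondrially encoded mRNAs 0.93 and YAP and TGF-beta targets 0.35. With an estimated correlation these 8 list calls were lost (adjusted p = 0.080 to 0.67). The call of the mitochondrial list was lost without U251 control 1, U87 control 1, U87 artesunate 1 or U87 artesunate 3 (adjusted p = 0.056, 0.063, 0.074 and 0.083). That of the YAP and TGF-beta list was lost without U87 control 1, U87 artesunate 1 or U87 artesunate 3 (adjusted p = 0.051, 0.059 and 0.054). In 1 of 100 drawn splits of the artesunate labels within the lines, the real one, as many genes differed (8478, highest other 7440). The count follows the U87 groups: it was 5837 to 7440 in the other splits that keep U87 artesunate and control libraries apart and at most 39 in the 85 that mix them. Splits of the former kind, 15 with the real one, are too few for a share under 0.05, and the share over all 100, set as the bound beforehand, tests the U87 change and not the difference.

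Of the 75 named genes, 5 had both groups of a line at or under 3 counts per library and were left out, 30 were called above 0 and 20 below. Above 0 (adjusted p from 1.5e-07 to 0.039) were AC023055.1 7.11, AC004922.1 5.90, FKBP2 4.59, CA9 4.35, CCDC9B 4.19, CAMK2N2 4.13, RTEL1-TNFRSF6B 4.04, DEPP1 3.81, PFKFB4 3.71, ANGPTL4 3.68, VEGFA 3.43, ELFN2 3.29, H2AFX 3.21, PKMYT1 3.19, NDRG1 3.08, BOP1 2.79, MCM5 2.44, CEBPB 1.88, PLTP 1.82, MT-CO3 1.65, F3 1.57, BAX 1.47, ITGB4 1.43, STC2 1.43, HK2 1.43, STEAP3 1.36, CDC20 1.29, AXL 1.21, PCBP1 1.202 and HMOX1 1.07. Below 0 (adjusted p from 2.9e-07 to 0.011) were LATS2 -0.53, SPDL1 -0.61, CCNB1 -0.73, RRN3 -0.81, DDIT3 -0.94, BNIP3L -1.22, TRIB3 -1.54, PSAT1 -1.64, CYBRD1 -1.69, SLC30A1 -1.94, MT1F -2.14, DNAJC15 -2.17, TP53INP1 -2.27, CTH -2.74, GPR1 -3.17, CYP1B1 -3.26, KLHL24 -3.77, RHOQ -4.34, SLC7A11 -4.66 and EREG -5.01. AC023055.1 had 6 counts in the U251 controls, PLTP 15 and 28 counts in U251, ITGB4 31 and 9 in U87 and EREG 12 and 5 in U251. All these differences are uncorrected for GC content. In the highest GC bin the median log2 fold change was 0.25 in U251 and -1.16 in U87, and in the lowest -0.19 and 0.70. Of all 8478 genes called for the difference, 3522 were called in the same direction after the GC and length correction and 280 in the other.

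In U87 the log2 fold changes fell with the GC content of the transcript. A GC trend as the whole cause of the integrated stress response, NRF2, metallothionein and DNA replication changes is excluded, since their medians kept at least 1.25 in size after the correction, but for the lower glycolysis genes it cannot be told apart from a change in the cells, with a corrected median of -0.33 between the bounds set beforehand. Variation of the trend between libraries of a group stays open too: rho, for which a bound was set beforehand, lay 0.137 below the controls, within their range of 0.682, as that explanation needs, while in the highest GC bin, chosen after rho was seen, each artesunate library lay at least 0.616 below the controls, whose range was 0.233, which alone would have argued against it under the bound added then, and the requirement that both measures agree was set after both were seen. A GC effect of library making that went with treatment, with no batch given, and a change in the cells that follows GC content stay open, the latter untested. For the count of called genes the 10 splits of 6 libraries are too few for a share under 0.05: 1 of 10 splits, the real one, reached 10005 genes in U87 (highest other 2), 1431 in U251 (4) and 11115 between the controls (0).

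Glycolysis genes rose in U251 and fell in U87, where the list call was lost with an estimated correlation (adjusted p = 0.36), as was that of the difference (adjusted p = 0.14). The medians differed by at least 1.35 under TMM, DESeq2's size factors and total counts, so the choice among these scalings does not make the difference. TMM factors ran only from 0.956 to 1.036, so this test could hardly have come out otherwise. It cannot exclude a scaling effect common to these methods. A GC trend as the whole cause of the difference is excluded, since the medians still differed by 0.873 after the correction. A biological hypothesis is that artesunate acts on these genes in opposite ways in the lines or at the doses given, which cannot be separated here, and the call of a fall in U87 ended with the correction, where the median went from -0.66 (quartiles -1.15 and -0.27) to -0.33 (-0.59 and 0.08), so the list moved toward 0 and its spread took in 0; GC content and length were corrected together, and which of them moved it was not tested.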

How the results depend on the processing

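The GC and length correction was chosen only after the result was seen. Fits without a library of a group that a comparison does not use were added after the others had been seen. The values on leaving out 1 library include them. The other tests of this part were planned. Causes were not tested unless stated. Genes called in U251 numbered 2310 with DESeq2 and 2892 with only the 6 libraries. They numbered 864 with no filter, 232 at an absolute log2 fold change of at least 1 and 506 at an adjusted p under 0.01, the last 2 by construction, and 652 to 2582 on leaving out 1 library, below 1431 without any U251 library and highest without U87 artesunate 2. At an absolute log2 fold change of at least 1, 4876 genes were called in U87, 5094 for the difference and 6432 between controls. At that threshold after the GC and length correction, 979 rose and 1611 fell in U87, and 1271 lay above and 680 below 0 for the difference. With a replicate block, which assumes a pairing that the labels do not state, 1169, 9724 and 8317 genes were called in U251, in U87 and for the difference. The block lies within a line, so that fit does not compare the control groups of the lines and gives no count between controls. On leaving out 1 library the counts were 9029 to 10468 in U87, 7739 to 9314 for the difference and 10315 to 11969 between controls.

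After the GC and length correction 5113 genes differed between the lines, the rho of the lines turned to 0.131, and genes higher in both were 437, lower in both 479, higher in U251 and lower in U87 191 and the reverse 73. On leaving out 1 library these 4 counts ran from 159 to 339, 130 to 317, 103 to 757 and 61 to 523. With an estimated correlation 6 lists were called in U251, 5 in U87, 0 for the difference and 0 between controls, where camera with the preset correlation called 10, 12, 8 and 6. With fry they were 12, 27, 25 and 27. After the GC and length correction 14 lists differed, and on leaving out 1 library 5 to 10 were called between controls. In U251 HMGCS1 turned to 0.017 with no filter and 0.16 after the correction, and ran from -0.059 to 0.061 on leaving out 1 library. In U87 CEBPB turned to 0.60, GPX4 to 0.88 and TFRC to -0.092 after the correction.

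With limma-trend on log2(FPKM + 1), which pulls low values toward 0, fold changes of some genes with a low level in 1 group were smaller. Examples are AC023055.1 (3.38 in U251), ELFN2 (-1.04) and KLHL24 (2.43) in U87. Of 1118 values of named genes under alternatives fixed beforehand other than leaving out a library, 1077 kept direction and side of the threshold, 38 lost the call, 2 gained it and 1 turned. Of 1128 on leaving out 1 library, these were 1098, 25, 3 and 2, and of 94 after the correction 86, 3, 1 and 4. Of 180 values of gene lists 147 kept the call and 33 lost it, of 432 on leaving out 1 library 407 and 25, and of 36 after the correction 34 and 2. Among the values on leaving out 1 library, 504 of named genes and 168 of lists left out a library outside the comparison. Such a library could change them only through the filter, the factors and the shared spread. Of these, 499 and 161 kept direction and side of the threshold, which raises the totals. The totals under alternatives fixed beforehand also hold values between controls under the replicate block, which do not test that comparison. Depth limits genes near 3 counts per library: no fold is given where both groups are at or under it, and folds of AC023055.1, UNC5B, CNR1 and FLNC rest on few counts in 1 group.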

Other observations

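Of the tests in this part, the GC and length correction was chosen only after the result was seen. On a scale where the mean of the U87 controls is 0 and the mean of the other artesunate libraries is 1, the median position over 4876 genes called at least 2-fold in U87 was 1.15, 0.809 and 1.07 for artesunate libraries 1, 2 and 3. Over the 5 mitochondrially encoded genes among them it was 1.61, 0.282 and 1.39. Of the authors' 269 calls in U251, 193 had an adjusted p of theirs under 0.05, of 3971 in U87 3853, and of 4502 between the controls 4443.

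Across all tested genes the fold changes of the lines were not positively related (rho -0.176). A hypothesis is that GC trends of opposite sign may hide a response that the lines share. After the GC and length correction rho was 0.131 (0.0907 to 0.138 on leaving out 1 library), above the 0.1 set beforehand, as this hypothesis needs. Without U251 artesunate 3 it was 0.0907, under that bound. Log2 fold changes had a rho with GC content of -0.628 in U87 and 0.412 in U251. Taking out trends of opposite sign raises the rho of the lines whether or not they share a response. The corrected rho therefore cannot decide the hypothesis. The jackknife SD of the uncorrected rho was 0.0764, and genes are not independent, so no p is given. Whether the trends come from library making or from the cells is not decided by this.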
